A study of Mus musculus with 16 samples.

How the data were processed

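Total RNA from 16 fresh-frozen subcutaneous tumours was hybridised by the authors to 1 array each, from 50 ng per tumour, per the labels' protocols. Hepa1-6 cells had been injected in 50% Matrigel into mice aged 5 weeks, and treatment began at a volume of 200 to 300 cubic mm, per the labels. Per the labels, the daily oral dose of cabozantinib was 30 mg/kg. The antibody and the hamster IgG were injected in 5 doses of 10 mg/kg, with 3 days between doses. Whether the Cabozantinib group also received IgG is not given in the sources used here. The deposited values are log2 probe set signals. RMA and the R package affy 1.62.0 are named in the submitters' processing notes, without their settings. The labels name the array as an Affymetrix mouse genome GeneChip, while the probe set names carry the suffix of its plate version, which holds perfect-match probes only. Any further filter or batch correction, and the scan dates, are not given in the sources used here.

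The table held 45141 probe sets for 16 arrays, with 0 missing values and 0 columns without a sample. Of these, 104 were control probe sets. Of the other 45037, 28898 were paired with 1 gene in the probe table, 551 with several and 15588 with none. The gene identifiers of 28689 of the 28898 were found in the RefSeq gene table, and 0 symbols needed an update. For each gene the probe set with the highest mean over the 16 arrays was kept, which left 17097 genes, of which 7180 had several probe sets. No genome build is named, so no coordinates are given. Array medians ran from 4.92 to 5.13, and the highest correlation between any 2 arrays was 0.994, so no array was a copy of another. Arrays carry no read depth, and the number of arrays limits the precision.

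Genes were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes on the log2 values in a model with 4 group means and no covariate. There were 5 pairwise comparisons, the interaction of the drugs, and each drug averaged over the other. Residual and prior degrees of freedom were 12 and 2.47. P values were adjusted by Benjamini-Hochberg over all 17097 genes within a comparison, with a threshold of 0.05. A second count, given as adjusted over the list alone, used only the members of a gene list. The comparisons, the 26 gene lists, the rule for naming genes and most of the other settings were fixed before the data were examined.

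The 26 lists marked neutrophils, neutrophil-attracting chemokines, monocytes and macrophages, T cells, cytotoxic lymphocytes, regulatory T cells and checkpoint receptors, B and plasma cells, dendritic cells, mast cells and eosinophils, interferon gamma response, type I interferon response, endothelial cells, pericytes and smooth muscle, fibroblasts and matrix, hypoxia and glycolysis, cell cycle, hepatocyte and fetal liver genes, kinases inhibited by cabozantinib, p53 targets, unfolded protein response, keratinocytes, skeletal muscle, adipocytes, red blood cells and platelets, ribosomal proteins, and immediate early genes. Each was tested against all other genes with limma's camera at a preset correlation between genes of 0.01, and again with a correlation estimated from the data. Fry, which asks whether a list moves on balance in 1 direction and makes no comparison with other genes, was run beside it. Each tumour also received a score per list, the mean over members of the log2 value minus the gene's mean over the 16 tumours. Scores were compared with two-sided exact permutation tests over tumours, adjusted over the 26 lists. None of these scores had an adjusted p under 0.05 in any of the 5 comparisons. The counts with an exact p under 0.05 were 6 for Cabozantinib against Placebo, 0 for AntiPD1 against Placebo, 8 for Combination against Placebo, 7 for Combination against Cabozantinib and 0 for Combination against AntiPD1.

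The named genes were chosen by a fixed rule. In each pairwise comparison it took up to 10 genes with the largest rise and 10 with the largest fall among those past the threshold, and up to 4 members past the threshold of each list. For a list that camera called with fewer than 2 such members, it took the 3 with the strongest statistic in the list's direction. If fewer than 5 genes passed, it took the 5 largest statistics on each side. A fixed panel of neutrophil, T cell, checkpoint, vessel, kinase, proliferation and liver genes was allowed everywhere. The 26 list sizes count measured members only.

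The gene test was checked on simulated data for Combination against Placebo, with 200 of 17097 genes changed. It recovered 42.4% of 66 genes changed by 0.5 on the log2 scale, 80.6% of 67 changed by 1 and 95.5% of 67 changed by 2. It made 12 false calls among unchanged genes and 0 in a comparison with no change, and camera called 0 of 25 unchanged lists. The changed genes were picked only from genes with a mean above every array's median, so the shares recovered do not cover genes near background. The simulated genes were drawn independently of each other, so this check does not cover lists whose members vary together. In the real data the estimated correlation within a list reached 0.958, for skeletal muscle. Scores, permutation tests and covariate fits were tested on simulated data as well, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9.

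The settings chosen beforehand were the mean of a gene's probe sets, the probe set with the largest variance, every probe set on its own, leaving out the 40% of genes with the lowest mean, renewed quantile normalization, median centring, eBayes with trend and robust options, array weights, a fit of only the 2 groups compared, a random block for the whole number in each sample's title, and leaving out each array in turn. After the data were seen, 3 more were added: leaving out the 3 arrays highest in muscle genes, muscle and adipocyte scores as covariates, and the score of 3 Y-linked genes as a covariate. The title numbers are not explained in the labels, and 8 arrays share one with another array. Results with other groupings of the tumours used all 35 splits or 100 drawn with a fixed seed. Probe sets that name no single gene were left out of the gene tests, since they could not be assigned to a gene.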

Results

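Gene expression was measured on 16 arrays, 1 per tumour, in male C57BL/6 mice whose flank tumours had grown from Hepa1-6, a mouse hepatocellular carcinoma line. The mice received hamster IgG (Placebo, n = 4), a hamster antibody that blocks the T cell checkpoint receptor PD-1 (AntiPD1, n = 3), the oral multikinase inhibitor cabozantinib (Cabozantinib, n = 5) or both drugs (Combination, n = 4). Tumours were taken on day 14. The comparisons ask what each drug changes alone, what each adds to the other, and whether the pair differs from the sum of the single drugs. The study's title points to neutrophils, so their genes are reported in every comparison. The deposited values were log2 array signals, with array medians between 4.92 and 5.13. After 1 probe set was kept per gene, 17097 genes were tested. Groups of 3 to 5 arrays limit the precision of every value below. A group mean under 4.92, the lowest array median, is not shown to be above background, and background then limits the size of a log2 difference. Among the genes named below this holds for Esm1, Mcpt2, Bmp2, Trp53i11 and Uty in Cabozantinib. In Combination it holds for Esm1, Mcpt2 and Gpihbp1, and in Placebo for Cyp2e1. It also holds for Igkv14-111, Ptn and Chga in every group but the highest.

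Skeletal muscle and adipocyte genes were uneven between tumours. The skeletal muscle score, the mean log2 deviation of 19 muscle genes from their means over the 16 tumours, was 4.33 in AntiPD1 replicate 2, 3.94 in Cabozantinib replicate 4 and 5.16 in Combination replicate 4. The Placebo tumours reached at most 0.66. The adipocyte score was 2.44 in Cabozantinib replicate 2 and 1.70 in Combination replicate 1. Signal from the Y chromosome also differed. The mean of Kdm5d, Eif2s3y and Uty, centred in the same way, was 0.54 ± 0.33 (SD, n = 4) in Combination, 0.58 ± 0.17 (SD, n = 3) in AntiPD1, -0.47 ± 0.52 (SD, n = 5) in Cabozantinib and -0.39 ± 0.50 (SD, n = 4) in Placebo. The exact permutation p of Combination against Cabozantinib was 0.0159, and 0.0794 after adjustment over 5 quality measures, with 4 of 4 Combination tumours above every Cabozantinib tumour. The array controls differed as well. In Cabozantinib against Placebo the hybridisation controls were 10.64 ± 0.28 (SD, n = 5) and 10.06 ± 0.35 (SD, n = 4), exact permutation p = 0.0317, and the labelling controls 9.24 ± 0.33 and 8.50 ± 0.60 (SD, same tumours), exact permutation p = 0.0476, both with adjusted p = 0.119. In AntiPD1 against Placebo the Actb 3' minus 5' difference, a sign of RNA quality, was 0.449 ± 0.003 (SD, n = 3) against 0.490 ± 0.036 (SD, n = 4), with 3 of 3 tumours below every Placebo tumour. Its exact permutation p was 0.0571, the smallest possible, and 0.143 after adjustment.

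**Figure D1:**
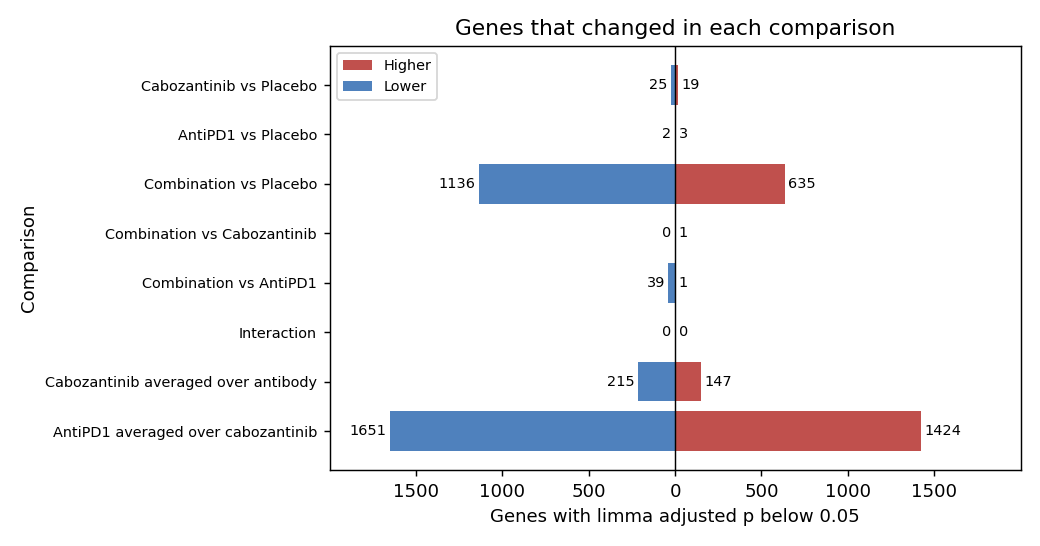
Genes with a limma adjusted p below 0.05 in each comparison, as counts of higher genes (right) and lower genes (left). Combination against Placebo gave 635 higher and 1136 lower genes, and the antibody averaged over the inhibitor gave 1424 and 1651.

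The first comparison asked what cabozantinib, an inhibitor of VEGF receptors, MET, AXL and KIT, changed when given alone. Several genes of blood vessels were lower. Esm1, which marks the tip cells of sprouting vessels, fell by 2.06 ± 0.21 on the log2 scale (SE), from 6.73 ± 0.47 (SD, n = 4) in Placebo to 4.66 ± 0.17 (SD, n = 5), a mean under every array's median, limma adjusted p = 0.00144. Gpihbp1, which anchors lipoprotein lipase to capillaries, fell by 2.24 ± 0.27 (adjusted p = 0.00409), and the junction gene Cdh5 by 1.33 ± 0.20 (adjusted p = 0.0142). The pericyte genes Rgs5 and Kcnj8 fell by 0.94 ± 0.14 and 0.70 ± 0.13 (adjusted p = 0.0141 and 0.0324). Mcpt2, a mast cell protease, fell by 3.29 ± 0.50 (adjusted p = 0.0142), to the level of background, and the globin gene Hbb-b2 fell by 3.09 ± 0.44 (adjusted p = 0.0141). For each of these genes, 5 of 5 Cabozantinib tumours lay below every Placebo tumour. Emcn, a sialomucin of capillaries and veins, fell by 1.65 ± 0.31 (adjusted p = 0.0381), in 4 of 5. Mcpt2 was also low without cabozantinib, at 4.80, 5.79 and 5.56 in the AntiPD1 tumours, against 6.08 or more in Placebo. The mast cell and eosinophil score, which leaves out Mcpt2, was not lower in AntiPD1. It was 0.64 ± 0.75 (SD, n = 3) there and 0.51 ± 0.63 (SD, n = 4) in Placebo.

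Some genes induced by low oxygen, and Gys1 and Gbe1, were higher in the same tumours. Gys1 and Gbe1, which build glycogen, rose by 0.76 ± 0.11 and 0.83 ± 0.14 (limma adjusted p = 0.0141 and 0.0261). Ero1a and P4ha2, which fold secreted proteins and hydroxylate collagen, rose by 0.74 ± 0.14 and 0.74 ± 0.12 (adjusted p = 0.0409 and 0.0169). Mxi1, which opposes MYC, rose by 0.44 ± 0.08 (adjusted p = 0.0418). All 5 Cabozantinib tumours lay above every Placebo tumour for these 5 genes. Egln3, the oxygen sensor, differed by 0.60 ± 0.12 (adjusted p = 0.0528) and Slc2a1, the glucose transporter, by 0.40 ± 0.08 (adjusted p = 0.063). Of the 22 hypoxia and glycolysis genes measured, 1 rose over all genes, 14 rose when adjusted over the list alone, and 22 had a positive log2 change. The list's score was 0.15 ± 0.08 (SD, n = 5) against -0.17 ± 0.13 (SD, n = 4), with an exact permutation p of 0.0159, the smallest this design allows, and 0.165 after adjustment over 26 lists. The list's camera call was lost with an estimated correlation (adjusted p = 0.229), and the array controls, given above, differed between the same groups.

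Neutrophil genes were higher on average in Cabozantinib tumours, but no single one passed. S100a8 and S100a9, which encode the calprotectin subunits abundant in neutrophils, were 9.72 ± 1.05 and 9.85 ± 1.16 (SD, n = 5) against 7.80 ± 0.67 and 7.59 ± 0.64 (SD, n = 4). The differences of 1.92 ± 0.52 and 2.26 ± 0.56 had limma adjusted p values of 0.136 and 0.105, with 5 of 5 tumours above every Placebo tumour. Of 26 neutrophil genes, 0 rose over all genes by limma and 4 rose when adjusted over the list alone. The neutrophil score was 0.10 ± 0.51 (SD, n = 5) against -0.52 ± 0.33 (SD, n = 4), exact permutation p = 0.0317, adjusted p = 0.165, between groups whose array controls also differed. Cabozantinib replicate 4, high in muscle, had the highest neutrophil score, 0.999, and the other 4 lay between -0.19 and -0.04. The neutrophil-attracting gene Cxcl2 differed by 1.56 ± 0.53 (adjusted p = 0.234). Cd274, which encodes the ligand PD-L1, differed by 0.68 ± 0.21 (adjusted p = 0.204), and Cd8a of killer T cells by 0.00 ± 0.28 (adjusted p = 1).

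In all, 19 genes rose and 25 fell in Cabozantinib against Placebo, 17 of the 44 by at least 2-fold, and 2218 genes had an unadjusted p under 0.05 where 855 were expected. Of 25 endothelial genes 3 fell over all genes and 12 fell when adjusted over the list alone. For 10 pericyte and smooth muscle genes these numbers were 2 and 4, for 29 cell cycle genes 0 and 20, and for 13 mast cell and eosinophil genes 0 and 8. Among cell cycle genes, Mcm5, a part of the replicative helicase, differed by -0.68 ± 0.16 (limma adjusted p = 0.102) and Mki67 by -0.16 ± 0.12 (adjusted p = 0.627), again beside the difference in array controls. With the preset correlation, camera called 10 of 26 lists, and all 10 calls were lost with an estimated correlation. Adjusted p values then were 0.229 for the endothelial, pericyte, mast cell and hypoxia lists, 0.33 for the cell cycle, 0.41 for immediate early genes, 0.522 for both neutrophil lists, and 0.824 for type I interferon and skeletal muscle genes. Fry called 4 lists, hypoxia, pericyte, endothelial and mast cell genes (adjusted p = 0.0142, 0.0212, 0.0367 and 0.0431). The count of 44 genes became 4 when only these 9 arrays were fitted, and 5 without Placebo replicate 3.

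**Figure D2:**
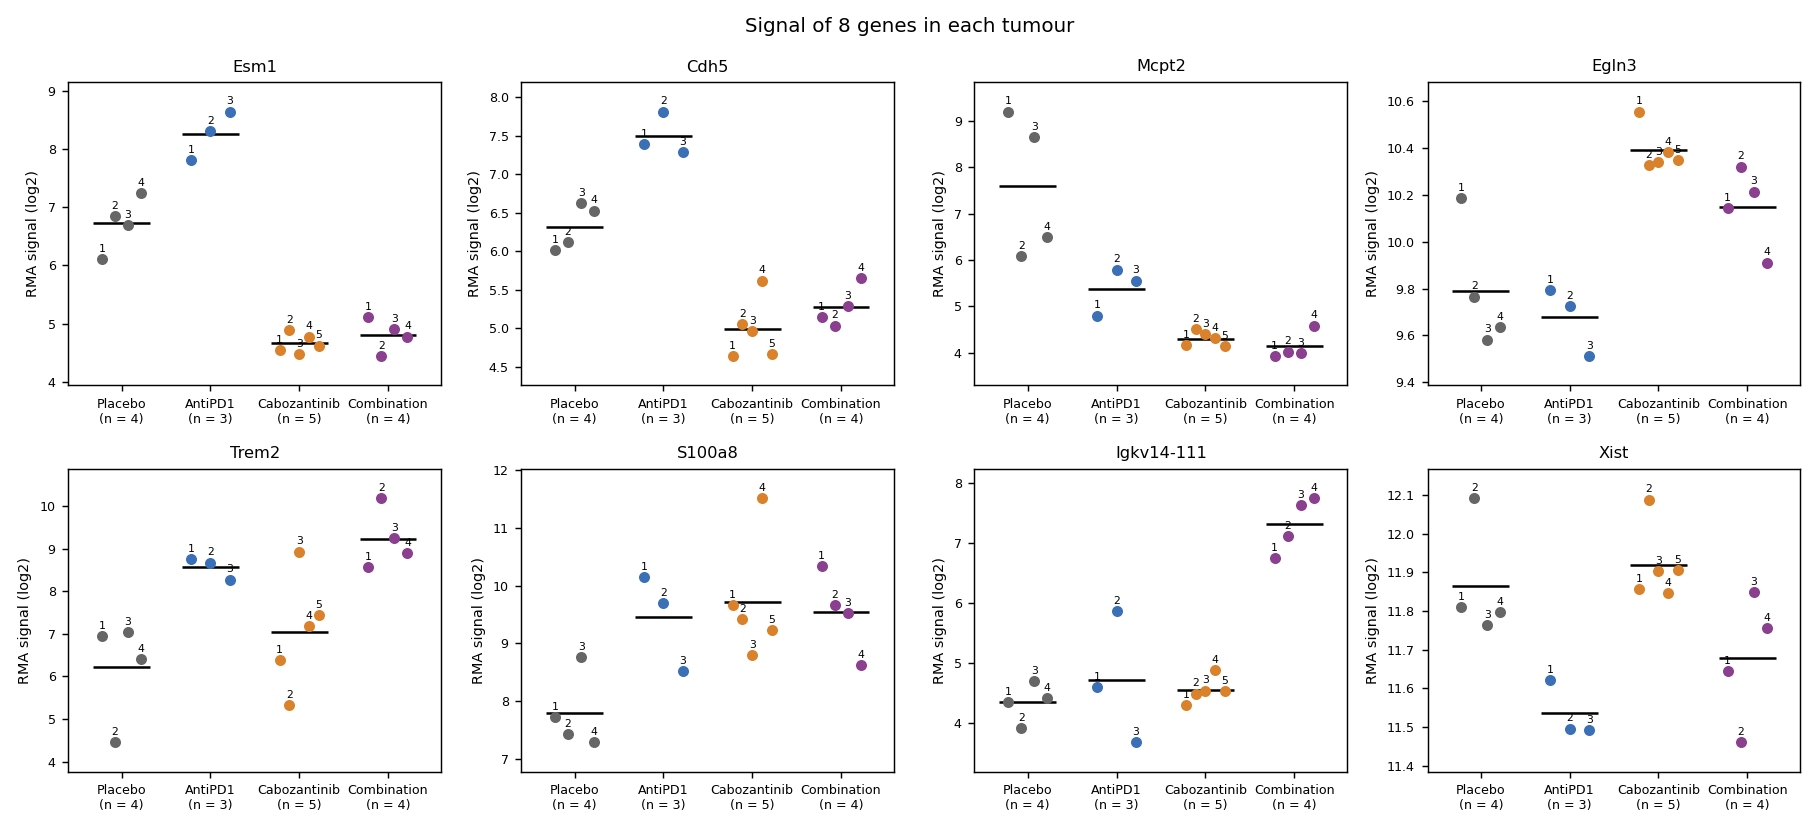
Log2 RMA signal of 8 genes in each tumour, by group, with replicate numbers beside the points and a line at each group mean. Esm1 averaged 4.66 in Cabozantinib and 4.81 in Combination, against 6.73 in Placebo and 8.26 in AntiPD1.

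The antibody alone changed 5 single genes past the threshold, a count that varied widely with the settings. Esm1 rose by 1.53 ± 0.24 (SE), to 8.26 ± 0.42 (SD, n = 3) from 6.73 ± 0.47 (SD, n = 4), limma adjusted p = 0.0469. Ptn, a heparin-binding growth factor, rose by 2.28 ± 0.35 and Chga, a granule protein of neuroendocrine cells, by 1.24 ± 0.18, both with adjusted p = 0.0469. Hsd17b7, an enzyme of cholesterol synthesis, fell by 0.93 ± 0.12 (adjusted p = 0.0331), and Clcn3, a chloride transporter of endosomes, fell by 0.48 ± 0.07 (adjusted p = 0.0469). For all 5 genes, 3 of 3 AntiPD1 tumours lay beyond every Placebo tumour. At an unadjusted p under 0.05 there were 3278 genes, against 855 expected.

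Genes of many host cell types had positive differences in AntiPD1 tumours, few of which passed singly. The Actb 3' minus 5' difference, given above, differed between the same groups. All 18 monocyte and macrophage genes had a positive log2 change, with a median of 1.21; 0 passed over all genes by limma and 11 rose when adjusted over the list alone. Itgam, an integrin of myeloid cells, differed by 2.01 ± 0.62 (limma adjusted p = 0.15), and Trem2, a receptor of lipid-handling macrophages, by 2.35 ± 0.73 (adjusted p = 0.151). The endothelial list had 25 of 25 positive changes, 1 of them past the threshold over all genes and 17 when adjusted over the list alone. Of 18 type I interferon genes, 17 were positive and 10 rose when adjusted over the list alone; Rsad2, an antiviral enzyme, differed by 1.87 ± 0.40 (adjusted p = 0.111). All 16 T cell genes were positive, and 0 passed in either way. Cd8a differed by 0.70 ± 0.32 (adjusted p = 0.258), Gzmb by 0.74 ± 0.51 (adjusted p = 0.44) and Ifng by 0.48 ± 0.45 (adjusted p = 0.589). Fibroblast genes had a median of 1.08 over 24 members, with Lum, a collagen-binding proteoglycan, at 2.74 ± 0.94 (adjusted p = 0.166). S100a8 differed by 1.66 ± 0.59 (adjusted p = 0.177), and of 26 neutrophil genes 4 rose and 1 fell when adjusted over the list alone.

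Camera with the preset correlation called 15 lists in AntiPD1 against Placebo, 13 higher and 2 lower, and none with an estimated correlation, where their adjusted p ran from 0.333 to 0.694. The 2 lower lists were cell cycle and ribosomal proteins, with medians of -0.18 and -0.08. Fry called 1 list, endothelial cells (adjusted p = 0.0289). With 3 tumours against 4, the smallest exact permutation p is 0.0571, so no list score could pass. Array weights were 3.23 for AntiPD1 replicate 1 and 0.87 and 0.85 for replicates 2 and 3, so replicate 1 dominated that group. The 5 genes became 1822 with array weights and 70 with only the 2 groups fitted, both settings fixed beforehand. They became 0 without AntiPD1 replicate 1 or 2, or without any 1 of several arrays of the other groups, and 30 without Cabozantinib replicate 3. The skeletal muscle list, called higher, reversed without AntiPD1 replicate 2 (adjusted p = 0.487). The Y-linked score was higher in 3 of 3 AntiPD1 tumours than in every Placebo tumour. With it as a covariate, chosen after the data were seen, several of the 15 lists reversed, T cells and fibroblasts among them. Regulatory T cell and interferon gamma lists were then called lower (camera adjusted p = 0.00558 and 0.000127).

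Of the 5 pairwise comparisons, Combination against Placebo gave the most genes past the threshold, and immunoglobulin and macrophage genes were among the largest rises. The light chain genes Igk-V21 and Iglv1 rose by 4.64 ± 0.84 and 4.71 ± 1.23 (SE; limma adjusted p = 0.0147 and 0.0339), each in 4 of 4 tumours above every Placebo tumour. Cd22, an inhibitory receptor of B cells, rose 3.08-fold (adjusted p = 0.0468), and Jchain, which joins secreted antibodies, differed by 3.68 ± 1.28 (adjusted p = 0.0761). Retnla, secreted by alternatively activated macrophages, rose by 3.65 ± 0.61 (adjusted p = 0.0135), to 11.65 ± 0.40 (SD, n = 4). Trem2, Itgam, Mrc1 and Arg1 rose by 3.01 ± 0.67, 2.21 ± 0.57, 1.88 ± 0.47 and 1.75 ± 0.35 (adjusted p = 0.0208, 0.0329, 0.0291 and 0.0158). Of 18 monocyte and macrophage genes, 7 rose over all genes and 15 rose when adjusted over the list alone. The list's score was 0.71 ± 0.31 (SD, n = 4) against -0.58 ± 0.55 (SD, n = 4), exact permutation p = 0.0286 and adjusted p = 0.0929, with 4 of 4 tumours above every Placebo tumour.

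Some neutrophil and checkpoint genes rose in Combination tumours as well. Clec4d, a receptor of neutrophils and monocytes, rose by 2.66 ± 0.60 (limma adjusted p = 0.0219), Csf3r, the receptor for the growth factor G-CSF, by 1.34 ± 0.28 (adjusted p = 0.0187), and the granule collagenase gene Mmp8 rose 2.82-fold (adjusted p = 0.0314). S100a8 and S100a9 differed by 1.73 ± 0.55 and 1.92 ± 0.59 (adjusted p = 0.0569 and 0.0504). In all, 5 of 26 neutrophil genes rose and 1 fell over all genes; 9 rose and 1 fell when adjusted over the list alone. The neutrophil score was 0.25 ± 0.36 (SD, n = 4) against -0.52 ± 0.33 (SD, n = 4), exact permutation p = 0.0571, adjusted p = 0.159. Tnfrsf9, which encodes the costimulatory receptor 4-1BB, rose by 1.70 ± 0.37 (adjusted p = 0.0198), Cd274 by 0.84 ± 0.23 (adjusted p = 0.0358) and Pdcd1lg2, the gene of PD-L2, by 1.02 ± 0.26 (adjusted p = 0.0309). T cell genes were positive in 16 of 16 members with 0 past the threshold; Cd8a differed by 0.48 ± 0.30 (adjusted p = 0.314), Gzmb by 0.51 ± 0.47 (adjusted p = 0.515) and Ifng by 0.79 ± 0.42 (adjusted p = 0.228).

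Some vessel and mast cell genes, and 15 of 29 cell cycle genes, were lower under both drugs. Esm1 and Gpihbp1 fell by 1.92 ± 0.22 and 2.40 ± 0.28 (both limma adjusted p = 0.00303), Kdr, the main VEGF receptor, fell by 1.13 ± 0.31 (adjusted p = 0.0389) and Kit, the receptor of mast cell growth, fell by 0.72 ± 0.21 (adjusted p = 0.0458). Mcpt2 fell by 3.46 ± 0.53 (adjusted p = 0.0103), again to the level of background, and was low in AntiPD1 tumours too, as given above. Of 29 cell cycle genes, 15 fell over all genes and 27 fell when adjusted over the list alone, with Kif20a, a motor protein of dividing cells, falling by 0.86 ± 0.20 (adjusted p = 0.0232). Of 25 endothelial genes 8 fell and 1 rose, of 10 pericyte genes 4 fell, and of 13 mast cell and eosinophil genes 3 fell. Camera did not call the endothelial list (adjusted p = 0.0548) or the pericyte list (adjusted p = 0.0766) with the preset correlation. It called the mast cell list (adjusted p = 0.0158), and lost it with an estimated correlation (adjusted p = 0.531). Of 25 hepatocyte and fetal liver genes 5 fell and 1 rose. Foxa1, a liver transcription factor, fell by 1.09 ± 0.22 (adjusted p = 0.0158), Alb by 0.22 ± 0.06 (adjusted p = 0.0361), and Cyp2e1, which adipocytes also express, rose by 3.78 ± 1.04 (adjusted p = 0.0385). Of 22 hypoxia and glycolysis genes 5 rose, among them Pfkp at 0.65 ± 0.13 (adjusted p = 0.015). The immediate early genes Fos and Jun rose by 1.45 ± 0.33 and 0.91 ± 0.18 (adjusted p = 0.0209 and 0.015). Their list was set beforehand as a mark of tissue handling. Its score was 0.22 ± 0.17 (SD, n = 4) against -0.275 ± 0.209 (SD, n = 4), with 4 of 4 Combination tumours above every Placebo tumour. The exact permutation p was 0.0286, and 0.0929 after adjustment, so a difference in handling is not excluded. Adipoq, secreted by fat cells, differed by 4.43 ± 1.57 (adjusted p = 0.0817), and 4 of 4 Combination tumours had a higher adipocyte score than every Placebo tumour (exact permutation p = 0.0286, adjusted p = 0.0929).

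In all, 635 genes rose and 1136 fell in Combination against Placebo, 331 of them by at least 2-fold. Camera called 17 lists with the preset correlation, 13 higher and 4 lower, and 0 with an estimated correlation, where adjusted p lay between 0.531 and 0.615; fry also called 0. The count of 1771 genes was 42 without Combination replicate 2 and 61 without Placebo replicate 2. It was 40, of which 35 were shared, with the muscle and adipocyte scores as covariates, and 1 with the Y-linked score as a covariate, both chosen after the data were seen. With the Y-linked score several lists also reversed, T cells and fibroblasts among them. Interferon gamma response was then called lower (camera adjusted p = 0.00541).

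**Figure D3:**
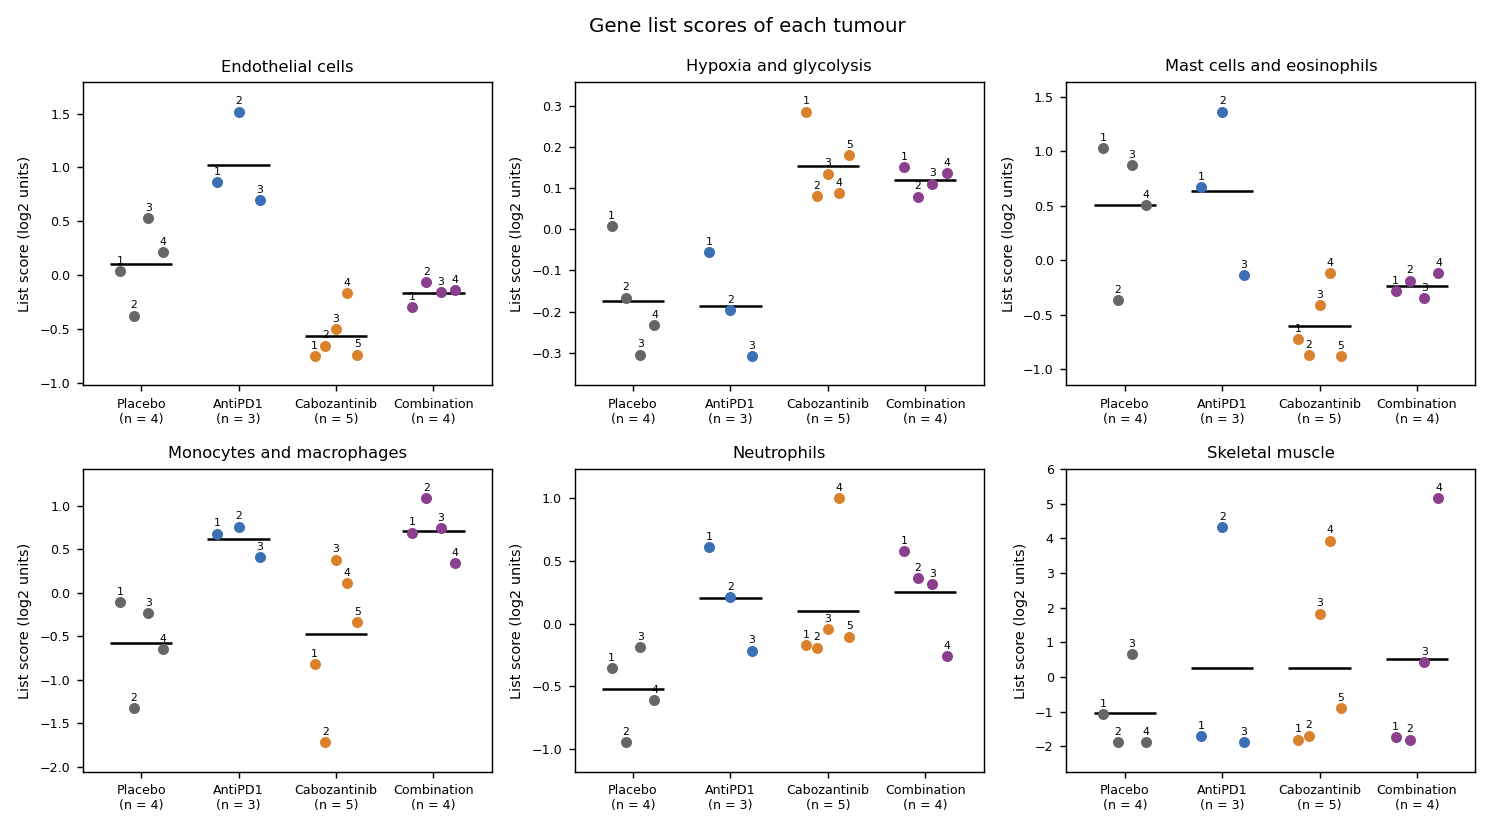
Scores of 6 gene lists in each tumour, in log2 units relative to the mean of the 16 tumours, by group, with replicate numbers beside the points and a line at each group mean. The endothelial score averaged -0.56 in Cabozantinib and -0.17 in Combination, against 0.10 in Placebo and 1.03 in AntiPD1.

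Adding the antibody to cabozantinib changed 1 gene past the threshold. Igkv14-111, an immunoglobulin light chain variable gene, rose by 2.76 ± 0.33 (SE), from 4.55 ± 0.21 (SD, n = 5) in Cabozantinib to 7.31 ± 0.46 (SD, n = 4) in Combination, limma adjusted p = 0.0129, in 4 of 4 tumours. All 5 Cabozantinib values, the highest 4.88, lay under every array's median, so the starting signal is not shown to be above background and the size of the rise is limited by that floor. Tnfsf13, the B cell survival factor APRIL, differed by 1.08 ± 0.16 (adjusted p = 0.052), and Ptger4, a prostaglandin receptor, by 1.90 ± 0.34 (adjusted p = 0.0733). Il23a, a cytokine subunit, differed by -0.91 ± 0.16 (adjusted p = 0.0733). At an unadjusted p under 0.05 there were 3853 genes, against 855 expected.

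Some macrophage and B cell genes were higher in Combination than in Cabozantinib tumours when each list was adjusted alone, and 0 of either list passed over all genes. Both camera calls were lost with an estimated correlation (adjusted p = 0.569). Of 18 monocyte and macrophage genes 0 passed over all genes by limma and 15 rose when adjusted over the list alone, with Adgre1, which marks mature macrophages, at 2.00 ± 0.50 (limma adjusted p = 0.0763). The score was 0.71 ± 0.31 (SD, n = 4) against -0.48 ± 0.83 (SD, n = 5), exact permutation p = 0.0317, adjusted p = 0.165, with 3 of 4 tumours above every Cabozantinib tumour. Of 13 B cell and plasma cell genes 6 rose when adjusted over the list alone, and the score was higher in 4 of 4 tumours (0.52 ± 0.42, SD, n = 4, against -0.31 ± 0.27, SD, n = 5; exact permutation p = 0.0159, adjusted p = 0.138). Of 25 hepatocyte and fetal liver genes 12 fell when adjusted over the list alone, among them Fgb of fibrinogen at -0.83 ± 0.24 (adjusted p = 0.0876). Neutrophil genes had a median of 0.01; S100a8 differed by -0.19 ± 0.52 (adjusted p = 0.867) and Cd8a by 0.48 ± 0.28 (adjusted p = 0.338). Camera called 11 lists with the preset correlation, 10 higher and 1 lower, and 0 with an estimated correlation (adjusted p between 0.569 and 0.592). Fry called 0 lists. The single call became 1955 genes without Cabozantinib replicate 3, 110 without Combination replicate 4, and 0 without any 1 of Cabozantinib replicates 1, 2 and 5 or Combination replicate 2. With the Y-linked score as a covariate, chosen after the data were seen, the count was also 0 and several lists called higher reversed. Those of regulatory T cells, interferon gamma response and fibroblasts were then called lower (camera adjusted p = 0.00187, 0.00187 and 0.000599).

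Adding cabozantinib to the antibody lowered vessel genes. Esm1 fell by 3.45 ± 0.24 (SE), from 8.26 ± 0.42 (SD, n = 3) in AntiPD1 to 4.81 ± 0.28 (SD, n = 4) in Combination, a mean under every array's median, limma adjusted p = 9.16e-06. Gpihbp1 and Cdh5 fell by 3.19 ± 0.31 and 2.22 ± 0.23 (adjusted p = 0.000249 and 0.000489), and Kdr by 2.00 ± 0.34 (adjusted p = 0.0209). Kit fell by 1.24 ± 0.23 (adjusted p = 0.039), Hbb-b2 fell by 2.86 ± 0.50 (adjusted p = 0.0273), and Ptn fell by 2.17 ± 0.35 (adjusted p = 0.0157). Mx1, an antiviral interferon target, fell by 1.06 ± 0.19 (adjusted p = 0.0336). Igkv14-111 was the 1 gene that rose, by 2.59 ± 0.38 (adjusted p = 0.00934), from an AntiPD1 mean under every array's median. For each of these genes 4 of 4 Combination tumours lay beyond every AntiPD1 tumour. Vegfa, the vessel growth factor induced by hypoxia, differed by 0.79 ± 0.18 (adjusted p = 0.132), S100a8 by 0.08 ± 0.59 (adjusted p = 0.996) and Cd8a by -0.22 ± 0.32 (adjusted p = 0.965).

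The endothelial list fell along with its single genes in this comparison. Of 25 endothelial genes 9 fell over all genes and 18 fell when adjusted over the list alone, with a median of -1.16, and this list alone kept its camera call with an estimated correlation (adjusted p = 0.0355). All 22 hypoxia and glycolysis genes were positive, and 0 rose over all genes and 9 rose when adjusted over the list alone (adjusted p = 0.0761 with an estimated correlation). All 18 type I interferon genes were negative, and 12 fell when adjusted over the list alone (adjusted p = 0.0761 with an estimated correlation). For 10 pericyte genes and 13 mast cell genes, 4 and 6 fell in that way (adjusted p = 0.0764 and 0.199 with an estimated correlation). All 29 cell cycle genes were negative with 0 past the threshold in either way (camera adjusted p = 2.95e-12, and 0.325 with an estimated correlation). Camera called 11 lists with the preset correlation, 3 higher and 8 lower. Fry called 5 lists, with adjusted p = 0.00212 for endothelial cells and 0.024 for both type I interferon and hypoxia genes. For both pericyte and red blood cell genes fry gave adjusted p = 0.028. In all 39 genes fell and 1 rose, 33 of the 40 by at least 2-fold, and 1233 had an unadjusted p under 0.05. With 4 tumours against 3 the smallest exact permutation p is 0.0571, so no list score could pass. The count was 13 without AntiPD1 replicate 2, and 14, of which 10 were shared, without the 3 tumours highest in muscle genes, a setting chosen after the data were seen.

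Cabozantinib against Placebo and Combination against AntiPD1 share no tumour, so they measure the inhibitor in separate animals. Of the 44 genes called in the first, 44 had the same sign in the second, and of the 40 called in the second, 40 had the same sign in the first. Over all genes, 65.8% had the same sign in both comparisons. Both called 11 genes lower and 0 higher. The calls come from 1 fit whose variances pool all 16 tumours, and with only the 2 groups compared in each fit the shared calls fell to 1. Among the 11 were Esm1, Gpihbp1, Cdh5, Emcn, Apold1, Trp53i11, Bmp2 and Hbb-b2. Across genes, which are not independent replicates, the log2 changes correlated with Pearson's r = 0.608. For the antibody, AntiPD1 against Placebo and Combination against Cabozantinib shared 0 calls, 5 of 5 and 1 of 1 calls kept their sign, and r across genes was 0.803. For this pair 74.1% of all genes had the same sign, so the signs of so few calls add little.

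Averaging the inhibitor over both antibody states set 9 tumours against 7. In that contrast 147 genes rose and 215 fell. Of 25 endothelial genes 15 fell, of 13 mast cell and eosinophil genes 6 fell, and of 22 hypoxia and glycolysis genes 9 rose over all genes; when adjusted over the list alone these were 18, 8 and 16. Kdr fell by 1.55 ± 0.22 (SE; limma adjusted p = 0.00273) and Pecam1 by 0.91 ± 0.20 (adjusted p = 0.0327), while Vegfa rose by 0.63 ± 0.12 (adjusted p = 0.0165). S100a9 differed by 1.28 ± 0.42 (adjusted p = 0.135), Cd274 by 0.56 ± 0.16 (adjusted p = 0.0925) and Cd8a by -0.11 ± 0.22 (adjusted p = 0.862). Of 9 treated tumours, 9 lay beyond the mean of their own control group for Kdr and Vegfa and 8 for Pecam1. Camera called 10 lists, and 0 with an estimated correlation, where the endothelial and hypoxia lists had adjusted p = 0.065; fry called 7.

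Averaging the antibody over both inhibitor states gave 1424 higher and 1651 lower genes. Of 18 monocyte and macrophage genes 17 rose over all genes. The same held for 13 of 24 fibroblast genes, 13 of 25 endothelial genes, 9 of 18 type I interferon genes, 4 of 18 cytotoxic lymphocyte genes and 3 of 16 T cell genes. Of 26 neutrophil genes 4 rose and 1 fell, and of 25 hepatocyte and fetal liver genes 6 fell. Csf3r rose by 0.88 ± 0.20 (SE; limma adjusted p = 0.0154) and Pecam1 by 0.73 ± 0.20 (adjusted p = 0.0259), and Vegfa fell by 0.42 ± 0.12 (adjusted p = 0.0309), each in 7 of 7 treated tumours relative to the mean of their control group. Cd3e and Cd8a differed by 0.57 ± 0.20 and 0.59 ± 0.22 (adjusted p = 0.0587 and 0.0699), and S100a8 by 0.73 ± 0.39 (adjusted p = 0.209). Camera called 15 lists, and 0 with an estimated correlation (adjusted p between 0.457 and 0.607). The count of 3075 genes was 602 without AntiPD1 replicate 2, and 0 with the Y-linked score as a covariate, a setting chosen after the data were seen.

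The interaction asked whether the pair of drugs differed from the sum of their single effects on the log2 scale. Limma called 0 genes, and 440 had an unadjusted p under 0.05 where 855 were expected. S100a8 had an interaction of -1.84 ± 0.79 (SE) and S100a9 of -1.96 ± 0.84, both with limma adjusted p = 1. The neutrophil score exceeded that of Placebo by 0.62 in Cabozantinib, 0.73 in AntiPD1 and 0.77 in Combination. Camera called 7 lists for the interaction with the preset correlation and 0 with an estimated correlation, the neutrophil list among them (adjusted p = 0.00039, and 0.949 with an estimated correlation).

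The lists left were called in some comparisons or in none. The list of receptor kinases inhibited by cabozantinib and their ligands was called in none of the 5 pairwise comparisons (camera adjusted p from 0.0779 to 0.569), although Kdr and Kit fell as given above. The same held for p53 targets (adjusted p from 0.0557 to 0.828) and for keratinocyte genes (adjusted p from 0.241 to 0.741). Unfolded protein response genes were called in Combination against AntiPD1 alone, with a median of 0.10 (adjusted p = 0.0358, and 0.199 with an estimated correlation). So were red blood cell and platelet genes, with a median of -0.05 and a mean of -0.42 (adjusted p = 0.0358, and 0.12 with an estimated correlation). Dendritic cell genes were called higher in AntiPD1 against Placebo and in Combination against Cabozantinib, with medians of 0.46 and 0.23 (adjusted p = 0.00762 and 0.00605, and 0.444 and 0.569 with an estimated correlation). The first call was also lost without AntiPD1 replicate 2 (adjusted p = 0.306), and both reversed with the Y-linked score as a covariate (adjusted p = 0.504 and 0.514). Interferon gamma response genes were called higher in AntiPD1 and Combination against Placebo and in Combination against Cabozantinib, with medians of 0.19, 0.17 and 0.18 (adjusted p = 0.00374, 0.00519 and 0.000308). With an estimated correlation these were 0.577, 0.532 and 0.592, and 0 genes of the list passed over all genes by limma in any of the 3. The first 2 calls were lost without Placebo replicate 4 (adjusted p = 0.0506 and 0.0581). With the Y-linked score as a covariate, chosen after the data were seen, the list was called lower in all 3 (adjusted p = 0.000127, 0.00541 and 0.00187). Ribosomal protein genes, meant as a reference group, had medians between -0.08 and -0.01 but were called lower in AntiPD1 and Combination against Placebo (adjusted p = 0.0189 and 0.0224, and 0.577 and 0.532 with an estimated correlation), with 16 of 16 members negative in each. Their score in Combination lay below every Placebo tumour in 4 of 4 tumours (exact permutation p = 0.0286, adjusted p = 0.0929).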

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

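Of the tests in this part, those of the macrophage score and of Igkv14-111 with the Y-linked score as a covariate, and the choice of the patterns to weigh, came after the results were seen.

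In 22 of 310 groups of 4 or 5 tumours, 1 tumour lay far from the others of its group, where chance alone gives about 1 in 20, or 15.5. Each value below is that tumour's gap to its nearest neighbour as a share of the group's range. Cabozantinib replicate 4 was apart for the neutrophil score (0.877), the neutrophil chemokine score (0.748), Csf3r (0.732), Cxcl2 (0.776), Emcn (0.794) and, on the low side, Rgs5 (0.742). It was also high in skeletal muscle genes, at a score of 3.94. Combination replicate 4, the highest in muscle at 5.16, was apart for hepatocyte genes (0.853) and Mcpt2 (0.860), and low for type I interferon genes (0.987) and Tnfrsf9 (0.830). Cabozantinib replicate 2 was high for the adipocyte score (0.799), Cabozantinib replicate 1 high for Egln3 (0.757) and Cabozantinib replicate 3 low for Kcnj8 (0.804). Combination replicate 2 was low for Emcn (0.887). Placebo replicate 1 was high for the T cell score (0.893) and Pdcd1lg2 (0.963), Placebo replicate 2 low for Cpa3 (0.835), Placebo replicate 3 high for Kif20a (0.839) and S100a9 (0.842), and Placebo replicate 4 high for the unfolded protein score (0.947), Adipoq (0.948) and Apold1 (0.838).

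For 7 gene lists the effect of the pair of drugs differed from the sum of the single effects by camera with its preset correlation. The adjusted p was 4.79e-11 for endothelial cells (median -0.54), 1.73e-10 for type I interferon genes (median -0.43), 0.000315 for hepatocyte genes (-0.20), 0.00039 for neutrophils (-0.30), 0.0165 for neutrophil chemokines (-0.45), 0.0377 for fibroblasts (-0.25) and 0.0431 for B cells and plasma cells (0.24). With an estimated correlation these became 0.475, 0.475, 0.949, 0.949, 0.972, 0.983 and 0.983, so 0 of 7 passed. Of the relabelled sets of tumours, 85 of 100 called as many lists as the real 7, and the highest other count was 20, so chance cannot be excluded for the number of lists called. The single lists were not compared with their own values under relabelling.

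Signal outside the gene tests also differed from Placebo. Of 16139 probe sets with no single gene, 35 passed in Cabozantinib, 4 in AntiPD1 and 658 in Combination. They were not assigned to genes.

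Other splits of the tumours into groups of the same sizes were used to weigh chance for the counts of genes. For Combination against Placebo only the real split, 1 of 35, gave as many as 1771, and the highest other gave 6. For Combination against AntiPD1 only the real split, 1 of 35, gave as many as 40, and the highest other gave 2. For cabozantinib averaged over antibody it was 1 of 100 (362, highest other 51). For the antibody averaged over cabozantinib it was 1 of 100 (3075, highest other 1852). Chance is an unlikely source of these counts. For AntiPD1 against Placebo 1 of 35 also gave as many as the real 5, and the highest other gave 2. A share of 1 of 35 is the smallest these designs allow, and none of these shares was adjusted over the comparisons. The 5 genes of AntiPD1 also became 0 without any 1 of several arrays, as given below, so chance is not excluded for them. For Cabozantinib against Placebo 4 of 100 gave as many as the real 44 and the highest other split gave 656, so chance is not firmly excluded. The split with 656 points to a structure of the samples. That split set Placebo replicates 2 and 4 and Cabozantinib replicates 1 and 2, the 4 tumours with the lowest macrophage scores of these 9, against the other 5. For Combination against Cabozantinib chance cannot be excluded (9 of 100; 1), and the highest other split gave 2487 genes, again a structure of the samples. That split put Cabozantinib replicate 3 with the 4 Combination tumours, against the other 4 Cabozantinib tumours. For the interaction the real count was 0, so all of the 100 splits (100) give as many by construction and the count decides nothing. The highest other gave 1103, with Placebo replicates 1, 3 and 4 and Cabozantinib 5 standing for Combination, Combination 1, 2 and 3 for AntiPD1, AntiPD1 3, Cabozantinib 1 and 4 and Placebo 2 for Placebo, and the rest for Cabozantinib.

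The shares for the counts of lists called by camera with the preset correlation were again unadjusted. In Combination against Placebo alone, only the real split, 1 of 35, called as many as 17 lists. That share is the smallest this design allows, and the highest other split called 16. At most, chance can be excluded there, and not firmly. It cannot in Cabozantinib against Placebo (60 of 100; 10, highest other 18), AntiPD1 against Placebo (6 of 35; 15, highest other 20), Combination against Cabozantinib (43 of 100; 11, highest other 18), Combination against AntiPD1 (7 of 35; 11, highest other 13), cabozantinib averaged over antibody (52 of 100; 10, highest other 16) or the antibody averaged over cabozantinib (16 of 100; 15, highest other 19). The median of the other splits was 8 to 11 lists, so the preset calls say little about the drugs by themselves.

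The first pattern weighed is the fall of endothelial genes with cabozantinib, where the list score's inhibitor coefficient over 16 tumours was -0.93 (95% interval -1.26 to -0.60). A smaller host share, read from the Y-linked score as a covariate, left -0.91 (-1.19 to -0.62). Muscle and adipocyte scores left -1.07 (-1.36 to -0.77), and the Actb 3' minus 5' difference with the hybridisation controls left -1.18 (-1.52 to -0.85). None of these 3 readings accounts for it. The labelling controls, which also differed between Cabozantinib and Placebo, and the Gapdh 3' minus 5' difference were not among the covariates. A loss of vessels, or lower expression of VEGF-dependent genes in the vessels present, may underlie it, and these data do not separate the 2.

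The second is the rise of macrophage genes with the antibody, with a coefficient of 1.19 (0.55 to 1.83). With muscle and adipocyte scores as covariates it was 1.28 (0.63 to 1.94), and with the same quality measures 1.11 (0.28 to 1.94). These values argue against either as the whole cause. With the Y-linked score as a covariate 0.041 (-0.50 to 0.58) remained, as a larger share of host cells in tumours given the antibody would give, and other host lists had positive mean changes too: fibroblasts 0.95, endothelial cells 0.66, T cells 0.62, cytotoxic lymphocytes 0.58, mast cells 0.25 and pericytes 0.15. Macrophages are host cells and carry the Y-linked signal themselves, so the covariate would take up their rise as well. A larger host share, more macrophages in particular, or both may be present, and these stay open.

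The third is Igkv14-111 in Combination tumours, with a coefficient against Cabozantinib of 2.76 (1.96 to 3.55), a size limited by Cabozantinib values under the array medians. With Jchain as a covariate, for more antibody-secreting cells of any clone, 1.90 (1.15 to 2.64) remained, with muscle and adipocyte scores 2.64 (2.05 to 3.22), and with the Y-linked score 2.45 (lower limit 1.30). A rise remained in each fit, although limma over all genes called 0 genes in this comparison with the Y-linked score. Outside Combination, Igkv14-111 lay near background, with means of 4.34 in Placebo, 4.72 in AntiPD1 and 4.55 in Cabozantinib. Jchain ranged from 5.06 to 10.2 in Cabozantinib. Values at the floor can flatten a relation to Jchain, so that fit cannot exclude more antibody-secreting cells of any clone. Jchain itself averaged 11.43 ± 0.79 (SD, n = 4) in Combination and 7.25 ± 2.11 (SD, n = 5) in Cabozantinib. Other light chain genes, Igk-V21 and Iglv1, also rose in Combination against Placebo, as given above. Against Placebo, a rise of light chain genes was thus not particular to this segment. Against Cabozantinib, Igkv14-111 was the only gene past the threshold. Whether plasma cells of the tumour or of the blood used this segment preferentially was not tested, since no sequence was measured. Hybridisation of related variable segments to the same probe set was not tested.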

How the results depend on the processing

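The settings with muscle, adipocyte or Y-linked scores as covariates, and the one without the 3 arrays highest in muscle genes, were chosen after the data were seen. The cause was not tested for any change given here unless stated. Counts with all arrays and the settings of the report are given beside the first mention of each comparison.

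Counts of genes moved with the choice of probe sets and filters. With the mean of a gene's probe sets, the 44 genes of Cabozantinib against Placebo became 82 (42 shared), the 5 of AntiPD1 against Placebo 8, the 1 of Combination against Cabozantinib 4, and the 11 inhibitor calls shared without and with antibody 18. With every probe set on its own these were 88 for Cabozantinib and 8 for AntiPD1 against Placebo, 710 for cabozantinib averaged over antibody (362) and 5465 for the antibody averaged over cabozantinib (3075). The probe set with the largest variance gave 1 gene for AntiPD1. Without the lowest 40% of genes there were 72 (40 shared), 1, 2 and 24 for Cabozantinib and AntiPD1 against Placebo and Combination against Cabozantinib and AntiPD1 (40). Renewed quantile normalization gave 2 for Combination against Cabozantinib, as did median centring and eBayes with trend and robust options. The shared inhibitor calls were 18 with median centring and 17 with trend and robust. Median centring changed the split of higher and lower genes to 14 and 31 for Cabozantinib against Placebo (19 and 25), 3 and 1 for AntiPD1 (3 and 2), and 93 and 212 for cabozantinib averaged over antibody (147 and 215).

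Array weights raised the counts to 71 for Cabozantinib, 1822 for AntiPD1 and 3059 for Combination against Placebo, 1441 and 155 for Combination against Cabozantinib and AntiPD1, 730 and 5037 for the averaged contrasts of inhibitor and antibody, and 25 for the shared inhibitor calls. The weights ran from 0.508 to 3.23. Fitting only the 2 groups compared gave 4, 70 (4 shared), 22 (14 shared) and 1 for Cabozantinib and AntiPD1 against Placebo, Combination against AntiPD1 and the shared calls. The labels do not say what the whole number in the titles means, and 8 arrays share one with another array. As a random block it had a consensus correlation of -0.103 and gave 1 gene for AntiPD1 against Placebo and moved no other count of genes past 1.5 times.

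Without the 3 arrays highest in muscle genes there were 37 genes for Combination against Cabozantinib, 14 against AntiPD1, 1613 for the averaged antibody and 6 shared inhibitor calls. Muscle and adipocyte scores as covariates gave 40 for Combination against Placebo (1771), 181 for the averaged inhibitor and 24 shared inhibitor calls. The Y-linked score as a covariate gave 260 for Cabozantinib, 0 for AntiPD1 and 1 for Combination against Placebo, 0 and 85 for Combination against Cabozantinib and AntiPD1, 929 for the averaged inhibitor, 0 for the averaged antibody and 36 shared inhibitor calls. The calls of the inhibitor were thus kept (44 of 44 and 362 of 362) and those of the antibody lost. The lowest Y-linked score with the antibody, 0.25, lay above the highest without it, 0.15. With and without the inhibitor the score was similar. As a covariate it would therefore take up differences of the antibody whatever their source.

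Camera with an estimated correlation called 0 lists in place of 10, 15, 17, 11, 7, 10 and 15 for Cabozantinib, AntiPD1 and Combination against Placebo, Combination against Cabozantinib, the interaction and the averaged inhibitor and antibody, and 1 in place of 11 for Combination against AntiPD1. Fry called 4, 1, 0, 0, 5, 0 and 4 for the first 3, Combination against Cabozantinib, Combination against AntiPD1, the interaction and the averaged antibody. With the Y-linked score as a covariate camera called 8, 10 and 8 for AntiPD1 and Combination against Placebo and the averaged antibody.

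Some lists reversed, and 6 of these passed the threshold in the opposite direction, which the adjusted p values under 0.05 below show. Skeletal muscle did so in Cabozantinib against Placebo with muscle and adipocyte scores as covariates (adjusted p = 0.958) and in AntiPD1 against Placebo without the muscle arrays (0.114), without AntiPD1 replicate 2 (0.487, in a range of 0.0014 to 0.487 over the arrays left out) and with the Y-linked score (0.252). Adipocytes did so in Combination against AntiPD1 with their own score as a covariate (0.861). The Y-linked score also reversed neutrophil chemokines (0.946), T cells (0.946), cytotoxic lymphocytes (0.906), regulatory T cells and checkpoint receptors (0.00558), dendritic cells (0.504), interferon gamma response (0.000127), fibroblasts (0.653) and ribosomal proteins (0.946) in AntiPD1 against Placebo. In Combination against Placebo it reversed T cells (0.666), cytotoxic lymphocytes (0.0702), regulatory T cells (0.666), interferon gamma response (0.00541), fibroblasts (0.253), hepatocyte genes (0.823) and skeletal muscle (0.519). In Combination against Cabozantinib it reversed T cells (0.413), cytotoxic lymphocytes (0.222), regulatory T cells (0.00187), dendritic cells (0.514), interferon gamma response (0.00187), endothelial cells (0.978) and fibroblasts (0.000599). Of the named genes, Pecam1 in the averaged antibody contrast reversed with that score (-0.0153, adjusted p = 0.998). No other named gene past the threshold reversed under any setting.

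Leaving out 1 array gave 5 to 91 genes for Cabozantinib against Placebo. The count was 91 without Placebo replicate 1, 23 without Placebo 2, 5 without Placebo 3, 14 without Placebo 4, 24, 29 and 23 without Cabozantinib 1, 2 and 3, and 29 without Combination 1. For AntiPD1 against Placebo the range was 0 to 30: 30 without Cabozantinib 3, 21 without AntiPD1 3, 10 without Cabozantinib 2, 3 and 2 without Combination 2 and 4, and 0 without Placebo 1, 2 or 3, AntiPD1 1 or 2, Cabozantinib 4 or 5, or Combination 1 or 3. For Combination against Placebo it was 42 to 2290: 42, 1058 and 1145 without Combination 2, 1 and 3, 61, 370 and 255 without Placebo 2, 3 and 4, and 1124 without AntiPD1 1. For Combination against Cabozantinib it was 0 to 1955: 1955 and 3 without Cabozantinib 3 and 4, 110 and 6 without Combination 4 and 3, 2 without Placebo 2, and 0 without Cabozantinib 1, 2 or 5 or Combination 2. For Combination against AntiPD1 it was 13 to 50: 26 and 13 without AntiPD1 1 and 2, and 23, 18 and 21 without Combination 1, 2 and 3. The interaction ranged from 0 to 1, with 1 gene without AntiPD1 2 or 3.

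The averaged inhibitor ranged from 158 to 443: 228, 168 and 202 without Placebo 2, 3 and 4, 202 and 158 without AntiPD1 1 and 3, and 231 and 188 without Combination 2 and 3. The averaged antibody ranged from 602 to 4258: 1741 and 1846 without Placebo 2 and 4, 1798 and 602 without AntiPD1 1 and 2, and 1506 without Combination 2. Shared inhibitor calls ranged from 5 to 16, with 5 without Placebo 3, 6 without AntiPD1 2 and 7 without Combination 1. Lists called ranged from 8 to 13, 12 to 18 and 14 to 19 for Cabozantinib, AntiPD1 and Combination against Placebo, 10 to 15 and 9 to 12 for Combination against Cabozantinib and AntiPD1, and 10 to 13 and 14 to 19 for the averaged inhibitor and antibody. For the interaction they ranged from 4 without Cabozantinib 4 to 11 without Cabozantinib 2. Scores with an exact permutation p under 0.05 ranged from 1 to 4 for Cabozantinib against Placebo (6) and from 3 to 6 for Combination against Cabozantinib (7), and were 0 for Combination against Placebo (8), where 3 tumours against 4 cannot pass. They stayed at 0 for AntiPD1 against Placebo and for Combination against AntiPD1.

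Of 186 named gene results, 180 kept their side of the threshold with the mean of probe sets, 181 with renewed quantile normalization, 178 with the title block, 141 with array weights, where 44 became stronger, and 137 of 172 with only the 2 groups, where 29 became weaker. With the settings added later these were 148 without the muscle arrays (31 weaker), 134 with muscle and adipocyte scores (47 weaker) and 124 with the Y-linked score (52 weaker and 1 reversed). Over 2976 results with 1 array left out, 409 became weaker and 55 stronger. Of the 186, 56 had several probe sets, and in 4 a further probe set had the opposite sign, 0 of them past the threshold. Groups of 3 to 5 arrays, and weak signals near the background of the arrays, limit what these comparisons can detect.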

Other observations

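The tests of the Y-linked genes and Xist, and the look at Cabozantinib replicate 3, were chosen after their values were seen.

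The mice were male, yet Xist, which silences an X chromosome in female cells, was at 11.46 or above in every tumour. It was 11.87 ± 0.15 (SD, n = 4) in Placebo, 11.92 ± 0.10 (SD, n = 5) in Cabozantinib, 11.68 ± 0.17 (SD, n = 4) in Combination and 11.54 ± 0.07 (SD, n = 3) in AntiPD1. Eif2s3y, a Y-linked gene, was 7.09 ± 0.64 (SD, n = 4) in Placebo, 7.18 ± 0.75 (SD, n = 5) in Cabozantinib, 8.40 ± 0.29 (SD, n = 4) in Combination and 8.32 ± 0.11 (SD, n = 3) in AntiPD1. A hypothesis is that Xist comes from the implanted tumour cells and the Y-linked signal from host cells, so that the pair may gauge the share of host cells. It predicts a negative relation. Over 16 tumours Pearson's r was -0.844 (permutation p = 6e-05, adjusted p = 0.00012) and Spearman's rho -0.856 (permutation p = 8e-05, adjusted p = 0.00016), and r was -0.835 without the 2 tumours farthest from the median of the Y-linked score. Of the 2 relations computed, the second used deviations from the group means, where r was -0.652 (permutation p = 0.00625, adjusted p = 0.00625), rho -0.553 (permutation p = 0.0283, adjusted p = 0.0283), and r without the 2 farthest tumours -0.715. These deviations were shuffled over all 16 tumours, with no allowance for the 4 group means removed. The p values of the second relation may therefore be too small. The labels give the sex of the mice and not that of the cell line, so the origin of Xist was not tested directly.

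If the Y-linked score does gauge host cells, then tumours given the antibody may have held a larger host share, and gene changes on its side would mix composition with regulation. With that score as a covariate, the antibody averaged over cabozantinib called 0 genes in place of 3075, whereas cabozantinib averaged over antibody called 929, with all 362 of its genes among them. The cause was not separated further. The score separates the tumours with the antibody fully from those without it, and is similar with and without the inhibitor. The loss of antibody calls alone therefore says little about their source.

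Cabozantinib replicate 3 had the highest macrophage score of its group, 0.38, against 0.71 ± 0.31 (SD, n = 4) in Combination and -0.48 ± 0.83 (SD, n = 5) in its own group. Its Y-linked score of 0.15 was also the highest of its group and lay below all 4 Combination tumours.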
